A study of Mus musculus with 4 samples.

How the data were processed

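Stranded total RNA libraries were sequenced in read pairs from 4 samples of sorted mouse CD4 T cells, 2 Tfh and 2 non-Tfh. The deposited files hold raw counts per Ensembl gene, and the submitters' processing notes name TopHat2, Bowtie2 and HTSeq with the genome build GRCm38 (mm10), with no versions, no annotation release and no strand setting for the counting. The values were whole numbers for 39179 gene identifiers, with library totals from 5725358 to 13360563. Symbols and positions came from an Ensembl-based annotation of GRCm38, which matched 37607 identifiers; the 1572 others held 0.209 to 0.228% of the counts and stayed in the library totals. Groups were taken from the sample labels.

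Tfh libraries were compared with non-Tfh libraries in R 4.3.3 with edgeR 4.0.16. Genes were kept by filterByExpr with the group, which left 11702, counts were scaled by the trimmed mean of M-values (TMM), and quasi-likelihood fits with robust dispersions were tested two-sided with Benjamini-Hochberg adjustment over all genes tested at 0.05. The model held the group alone, with 2 residual degrees of freedom, because no label ties libraries of the same number to a shared animal, pool or day. Levels are TMM-scaled CPM as mean ± SD with n = 2 per group, and log2 fold changes are Tfh over non-Tfh ± SE. This SE is the absolute log2 fold change over the square root of the quasi-likelihood F, so it adds no information on precision beyond the test. The biological coefficient of variation was 0.156. Where a group had no counts, the fold is a lower bound against a floor of 3 counts over that group; where it had 1 to 3 counts, the ratio of pooled counts is given with its exact 95% binomial interval, and the fitted value is not used. With a library left out, a log2 fold change is given only where each group kept more than 3 counts. Shares of receptor segment counts have exact (Clopper-Pearson) 95% intervals.

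Gene lists, 29 of pathways and 15 of cell type markers with 765 members, of which 753 matched an identifier, came from general knowledge of T helper cells. They covered the Tfh program, Bcl6 antagonists, Th1 and cytotoxic, Th2, Th17 and Treg genes, lymph node homing and egress, inflammatory tissue migration, naive and memory genes, IL-2 and STAT5, coinhibitory receptors, costimulation, T cell receptor response, immediate early and stress genes, G1/S, G2/M, histones, apoptosis, glycolysis, mitochondrial respiration, cholesterol synthesis, interferon-stimulated genes, TGF-beta and SMAD, cytokines and helper factors, Notch and Wnt, adenosine and purine receptors, ribosomal proteins, mitochondrially encoded genes and structural RNA, and markers of T, CD8 T, gamma delta T, NK, B, germinal centre B, plasma, macrophage, dendritic, granulocyte, mast, erythroid, stromal, endothelial, and epithelial or fat cells. Cxcr5 and Pdcd1, which the sort selected on, were left out of every list. The 34 lists with at least 5 tested members were tested with camera (limma 3.58.1) at a preset inter-gene correlation of 0.01, adjusted over the 34, and again with a correlation estimated per list. The second form tests each list on the residual degrees of freedom, here 2, and so has little power. Medians of the lists were the same with genes of no counts in a group set to their bound.

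The comparison, the lists, the alternatives and the rule for naming genes were fixed before the data were examined. The rule took the sorting genes, the 12 largest changes in each direction among called genes with a mean of at least 5 CPM and no overlap between groups, leaving out predicted genes, pseudogenes, receptor and immunoglobulin segments and histones, and up to 4 called members of each list, or the 2 most abundant where none was called. Another 21 genes were named after their values were seen, among them Bcl6, Tbx21, Klf2, Foxp3, Gata3 and Il17a, and the neighbours and family members given as further observations. Some further genes that the rule took are not reported here, with no others in their place.

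The alternatives were RLE and upper-quartile scaling, DESeq2 1.42.0, limma-voom, no count filter, a filter of at least 5 CPM in 2 libraries, dispersions without the robust option, a block for the library number, a test against a minimum fold of 1.5, counts without mitochondrial and the 10 most abundant genes, and each library left out in turn. Chromosomal neighbours and gene families were tested in Python 3.11.15 with pandas 2.3.3, numpy 2.4.6 and scipy 1.17.1, and figures were drawn with matplotlib 3.10.9.

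The code was tested on simulated data of the same depths with 200 changed genes. The edgeR fit recovered 10.2% of 49 genes changed 1.5-fold, 69.4% of 49 changed 2-fold, 86.0% of 50 changed 4-fold and 100% of 50 changed 8-fold. Of its 157 calls 25 (15.9%) were unchanged genes when dispersions were drawn per gene, and 8 of 143 (5.59%) when they followed the trend, so at n = 2 the share of false calls can exceed the nominal 0.05. With random genes changed camera called 0 of 33 lists. With 1 list doubled it called 3, that list among them. The simulated genes were drawn independently of each other, so neither result shows how often camera calls lists of correlated genes.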

Results

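RNA was sequenced from ovalbumin-specific CD4 T cells of OT-II mice, which carry a transgenic T cell receptor, after transfer into C57BL/6 hosts and immunisation with nitrophenol-coupled ovalbumin. On day 8 the transferred cells were sorted from pooled inguinal nodes into CXCR5+ PD-1+ T follicular helper (Tfh) cells, which help B cells in germinal centres, and CXCR5- PD-1- activated (non-Tfh) cells. There were 2 libraries per group, numbered T32 and T53 in both groups, and the labels do not say what these numbers mark. The total gene count was 12354113 in Tfh T32, 5725358 in Tfh T53, 13360563 in non-Tfh T32 and 8636056 in non-Tfh T53. Between 14613 and 15946 genes had at least 1 count in a library, and 1 count was worth 0.0748 to 0.175 CPM (counts scaled to library size).

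The receptor genes matched the transgenic origin of the cells. Of the counts on beta-chain V segments, those on Trbv12-1 and Trbv12-2 made up 93.3% in Tfh T32 (exact 95% interval 92.6 to 94.1%), 91.9% in Tfh T53 (90.5 to 93.2%), 90.7% in non-Tfh T32 (89.7 to 91.5%) and 90.4% in non-Tfh T53 (89.1 to 91.6%). Of the counts on alpha-chain V segments, the Trav14 genes made up 93.0% (92.6 to 93.3%), 92.0% (91.3 to 92.5%), 93.2% (92.8 to 93.5%) and 91.6% (91.1 to 92.1%) in the same order. The segments of each family are nearly identical and share reads, so they were summed. Intervals and count floors, here and below, cover counting error only.

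Of the genes of the sorting markers, Cxcr5 and Pdcd1 differed as the gates did, which checks the labels and is no finding. Cxcr5, the receptor for the B cell follicle chemokine, measured 730.4 CPM ± 25.1 in Tfh cells and 54.3 ± 2.41 in non-Tfh cells (mean ± SD, n = 2 per group), a 13.4-fold difference (log2 fold change 3.75 ± 0.135 SE, adjusted p = 0.000182). Pdcd1, which encodes PD-1, measured 557 CPM ± 28.2 against 55.3 ± 2.54, a 10.1-fold difference (adjusted p = 0.000222). Cd44 measured 275 CPM ± 62.2 against 191 ± 38.5 and did not pass the test (adjusted p = 0.21). Thy1, whose product marks the transferred cells, fell 2.51-fold, from 224 CPM ± 6.61 in non-Tfh to 89.6 ± 5.65 in Tfh cells (log2 fold change -1.33 ± 0.116, adjusted p = 0.00243). The gates as described differ in CXCR5 and PD-1 only, not in Thy1. Whether sorting on these markers also selected cells by Thy1 level was not tested.

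The comparison of both sorted groups asked which genes set antigen-specific Tfh cells apart from activated cells of the same receptor that had not become Tfh cells. Tfh cells expressed more of the Tfh regulator Bcl6, the helper cytokines Il21 and Il4 and the receptors Tigit and Cd160, and less of the cytokine receptors Il7r and Il2ra, the chemokine receptors Ccr7 and Ccr2, the IL-18 receptor chain Il18rap and the Th17 cytokine gene Il17f. Bcl6, the transcription factor that directs the Tfh fate, rose 7.51-fold (log2 fold change 2.91 ± 0.223, adjusted p = 0.00187), from 40.2 CPM ± 7.34 to 301 ± 73.2. Il21, whose product acts on germinal centre B cells, rose by 3.90 ± 0.145 on the log2 scale (adjusted p = 0.000182), from 25.1 CPM ± 0.71 to 377 ± 41.7. Ccr2, a receptor for inflammatory chemokines, fell 64.2-fold (-6.00 ± 0.22, adjusted p = 0.000182), from 97.7 CPM ± 7.67 to 1.41 ± 0.504. Of 11702 genes tested, 994 passed an adjusted p of 0.05, 523 higher and 471 lower in Tfh cells, and 2570 had an unadjusted p under 0.05. Changes of at least 2-fold numbered 333 up and 332 down, and changes of at least 8-fold numbered 87 up and 110 down. All 994 had the same sign within T32 and within T53, which a call with 2 libraries per group largely implies. Without the Tfh T53 library, 298 genes were higher and 247 lower. The labels do not say whether the libraries came from separate animals, so the p-values measure only the spread between these samples.

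**Figure D1:**
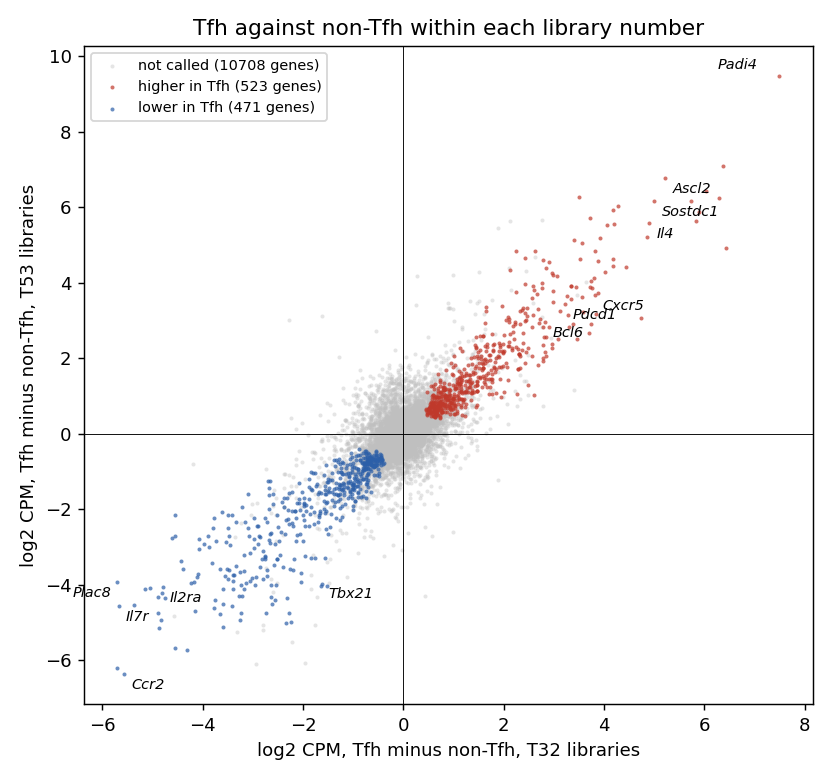
Difference in log2 CPM between Tfh and non-Tfh cells within T32 (horizontal axis) and within T53 (vertical axis), 1 point per tested gene, prior count 2. The 523 genes called higher (red) and the 471 called lower (blue) had the same sign on both axes; grey points are the 10708 tested genes not called.

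The genes with the largest increases included a peptidylarginine deiminase, Padi4 (ENSMUSG00000025330, GRCm38 chromosome 4, 140745865 to 140774236), which rose 385-fold from 0.859 CPM ± 0.578 to 364 ± 140 (log2 fold change 8.59 ± 0.503, adjusted p = 0.00187). Asb2, part of a ubiquitin ligase (ENSMUSG00000021200, chromosome 12, 103321142 to 103356001), rose 86.7-fold from 1.67 CPM ± 0.351 to 142 ± 22.6 (6.44 ± 0.222, adjusted p = 0.000182). Ascl2, a transcription factor that induces Cxcr5 (ENSMUSG00000009248, chromosome 7, 142966829 to 142969264), had no counts in the non-Tfh libraries and 210 counts in the Tfh libraries, at least 107-fold higher against a floor of 3 counts over the group. Akap6, an anchoring protein for protein kinase A, rose 172-fold and the nuclease Dnase1l3 rose 42.2-fold. Genes with 1 to 3 counts in non-Tfh cells were Sbk2, with a ratio of 317 (95% counting interval 56.4 to 12581), Vwde, with 178 (60.6 to 868), and Cpeb1, an RNA-binding protein, with 147 (49.8 to 714). The transcript Kirrel3os rose 90.9-fold. It lies antisense to Kirrel3, and the strand setting of the counting is not given, so its counts may be reads of Kirrel3. The call of Ascl2 was lost without non-Tfh T32 (adjusted p = 0.157) and without non-Tfh T53 (0.14), and that of Kirrel3os likewise (0.134 and 0.139). Without non-Tfh T32 the log2 fold change of Padi4 was 9.61 and that of Kirrel3os 5.49, and without Tfh T53 that of Kirrel3os was 5.76.

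Among the largest decreases, Nhsl2 (chromosome X, 101849385 to 102092055) had no counts in Tfh cells and 12.4 CPM ± 3.12 in non-Tfh cells, at least 73.0-fold lower. Il7r, the receptor for the survival cytokine IL-7 (ENSMUSG00000003882, chromosome 15, 9505788 to 9530176), fell 35.6-fold from 203 CPM ± 30.8 to 6.31 ± 4.18 (log2 fold change -5.15 ± 0.443, adjusted p = 0.00581). Il2ra, the high-affinity chain of the IL-2 receptor (ENSMUSG00000026770, chromosome 2, 11642807 to 11693193), fell 24.2-fold from 54.5 CPM ± 22.8 to 2.22 ± 0.177 (-4.59 ± 0.384, adjusted p = 0.00265). Smad7, an inhibitor of TGF-beta signalling, fell 25.4-fold, the sialyltransferase St8sia6 fell 34.7-fold, the fatty acid ligase Acsbg1 fell 41.5-fold and Anxa1, a phospholipid-binding protein, fell 36.7-fold. Fam129b fell 31.9-fold, Dennd5a, a Rab exchange factor, fell 27.2-fold and Ifitm2, one of several similar neighbouring genes, fell 29.2-fold. Plac8, with 3 counts in Tfh cells, had a ratio of 73.0 (24.7 to 356) in favour of non-Tfh cells. The call of Il7r was lost without non-Tfh T32 (adjusted p = 0.0661) or non-Tfh T53 (0.113), and that of Smad7 likewise (0.0541 and 0.0681). Without Tfh T32 the log2 fold change of Anxa1 was -4.43, that of Il7r -4.45, that of St8sia6 -4.53, that of Dennd5a -4.12 and that of Smad7 -3.85. Without Tfh T53 that of Il7r was -5.90 and that of Smad7 -5.53. Without non-Tfh T53 that of Ifitm2 was -4.17.

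**Figure D2:**
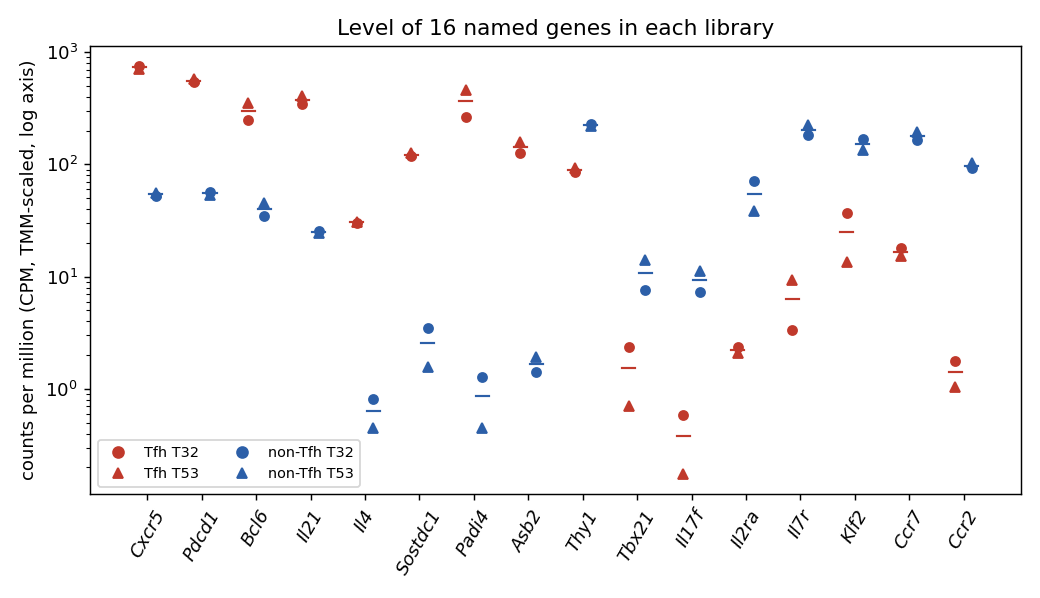
CPM scaled by trimmed mean of M-values (log axis) of 16 genes in Tfh and non-Tfh cells; circles are T32, triangles T53 and the short line is the mean of 2. Bcl6 lay at 301 CPM in Tfh and 40.2 in non-Tfh cells, and Il7r at 6.31 and 203.

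Groups of genes were tested against all other genes with camera at a preset inter-gene correlation: 16 of 34 lists passed, 6 higher and 10 lower in Tfh cells. With a correlation estimated for each list none passed, with 6 at an unadjusted p under 0.05 and a smallest adjusted p of 0.194. The p estimated in this way follows each called list. It rests on the 2 residual degrees of freedom, so few lists could pass. A lost call therefore does not show by itself that correlation between genes produced it. The Bcl6 antagonists had an estimated correlation of 0.000427, below the preset 0.01, yet their unadjusted camera p went from 3.40e-11 to 0.0193. Among the called lists the estimates ran from -0.101 (germinal centre B cell) to 0.944 (interferon-stimulated genes). They were 0.914 for ribosomal proteins, 0.398 for cytokines and helper factors and 0.371 for glycolysis. Where the preset lies far below the estimate, correlation and the few degrees of freedom cannot be told apart as the source of a lost call. Of the Tfh program, genes known from Tfh cells in general, 21 of 32 tested members rose and none fell, and adjusted over the list alone 24 rose and 3 fell (median log2 fold change 1.29, adjusted p = 7.97e-49, and 0.194 with an estimated correlation). Sostdc1, a Wnt and BMP antagonist, rose 45.5-fold (5.51 ± 0.288), Il4 rose 45.0-fold (5.49 ± 0.273) and Fam43a rose 18.5-fold (4.21 ± 0.193). Cytokines and helper factors were higher, with 4 of 13 members up and 1 down, and 5 and 1 adjusted over the list alone (median 0.30, or -0.071 without Tfh T53, adjusted p = 1.16e-09, and p = 0.437 with an estimated correlation). Besides Il21 and Il4, Lif, an IL-6 family cytokine, rose 3.77-fold (1.91 ± 0.201) and Tnfsf8, the CD30 ligand, rose 2.83-fold. The member that fell was the Th17 cytokine gene Il17a. Il21, Il4 and Tnfsf8 are also in the Tfh program, and other lists share members too, so the list calls are not independent. Without non-Tfh T32 the log2 fold change of Sostdc1 was 6.27.

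The list of Bcl6 antagonists, factors that oppose the Tfh fate, was lower: 11 of 16 members fell and 1 rose, and 13 and 3 adjusted over the list alone (median -1.51, adjusted p = 2.31e-10, and p = 0.219 with an estimated correlation). Id2, an inhibitor of basic helix-loop-helix factors, fell 6.98-fold (log2 fold change -2.80 ± 0.159), and Prdm1, which encodes Blimp-1, fell 7.17-fold from 6.60 CPM ± 0.262 to 0.804 ± 0.642. Klf2, a factor that drives S1pr1, fell 5.80-fold (adjusted p = 0.0443). The member that rose was P2rx7, an ATP-gated channel linked to cell death in Tfh cells, 5.09-fold (2.35 ± 0.134). The call of Klf2 was lost without non-Tfh T32 (adjusted p = 0.343), without non-Tfh T53 (0.377) and without a low-count filter (0.331); without Tfh T32 the log2 fold change of Klf2 was -3.49.

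The Th1 and Th17 lists were lower. In the Th1 and cytotoxic list 10 of 21 members fell and none rose, and 15 and 0 adjusted over the list alone (median -2.36, adjusted p = 3.55e-13, and p = 0.252 with an estimated correlation). Il18rap, a chain of the IL-18 receptor, fell 14.6-fold (-3.87 ± 0.282), its partner Il18r1 fell 15.6-fold and Runx3 fell 6.57-fold. Tbx21, the Th1 regulator T-bet, fell 6.30-fold (-2.65 ± 0.536, adjusted p = 0.0366). In the Th17 list 8 of 12 members fell and 1 rose, and 10 and 1 adjusted over the list alone (median -2.72, adjusted p = 1.27e-07, and p = 0.308 with an estimated correlation). Il17f fell 20.4-fold (-4.35 ± 0.507), Il23r, the IL-23 receptor, fell 6.12-fold (-2.61 ± 0.377), Ahr, the aryl hydrocarbon receptor, fell 2.74-fold, and Il17re fell 15.4-fold. Il17a had 1 count in Tfh and 55 in non-Tfh cells (counting interval of the ratio 7.49 to 1749). Calls were lost without non-Tfh T32 for Il18r1 (adjusted p = 0.152) and Runx3 (0.0655), and without non-Tfh T53 for Il18r1 (0.2), Runx3 (0.0977) and Tbx21 (0.0634). They were lost without Tfh T32 for Il17re (0.07) and Il17a (0.0724), and without Tfh T53 for Tbx21 (0.0527), Il17re (0.0583) and Il17a (0.0595). Without Tfh T32 the log2 fold change of Il18r1 was -5.02, that of Il18rap -4.58, that of Runx3 -3.48 and that of Tbx21 -3.91, and the Th1 median was -3.25. Without non-Tfh T32 the log2 fold change of Il17re was -3.17, and the Th17 median was -1.95. With limma-voom Tbx21 (adjusted p = 0.0652) and Il17re (0.0509) lost their calls, as did Tbx21 (0.0651) and Runx3 (0.0635) with a replicate block and Il18r1 (0.0994) without a count filter.

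In the Treg list 4 of 15 members fell and 2 rose, and 8 and 3 adjusted over the list alone (median -0.58, adjusted p = 0.0456, and p = 0.552 with an estimated correlation). Capg, an actin-capping protein, fell 4.83-fold (-2.27 ± 0.24), Itgae, the integrin CD103, had no counts in Tfh cells and was at least 41.9-fold lower, and Ikzf2, the factor Helios, rose 3.42-fold (1.77 ± 0.19). Foxp3, the Treg regulator, had 1 count in Tfh and 35 in non-Tfh cells (counting interval of the ratio 4.65 to 1125) and did not pass the test (adjusted p = 0.0601), but passed without non-Tfh T32 (0.0428). The list lost its call without Tfh T32 (adjusted p = 0.658), without Tfh T53 (0.0537) and under a stricter count filter (0.717, with a median of 0.36), and Itgae lost its call without Tfh T32 (0.0576). Of 7 Th2 genes 1 rose, the Tfh cytokine Il4, and 3 fell, and 1 and 5 adjusted over the list alone (median -1.10); the list did not pass (adjusted p = 0.356), but did without non-Tfh T32 (0.0211). The members that fell were Il4ra, 2.13-fold (-1.09 ± 0.146), the chemokine receptor Ccr4, 2.15-fold (-1.10 ± 0.237), and Il1rl1, with 1 count against 43 (counting interval of the ratio 5.79 to 1374). Gata3, the Th2 regulator, measured 49.8 CPM ± 6.00 against 59.9 ± 1.72 and did not pass (adjusted p = 0.309). Ccr4 lost its call without Tfh T32 (adjusted p = 0.0892), Tfh T53 (0.175) or non-Tfh T32 (0.0658) and with limma-voom (0.0634), and Il1rl1 without Tfh T32 (0.198), Tfh T53 (0.0555) or non-Tfh T53 (0.0979), with limma-voom (0.066) and without the robust option (0.0523).

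The lists for movement and for the resting state were lower. Of 27 genes for migration to inflamed tissue, 15 fell and 1 rose, and 18 and 2 adjusted over the list alone (median -1.41, adjusted p = 2.47e-15, and p = 0.194 with an estimated correlation). Cxcr6, a chemokine receptor, fell 5.12-fold (-2.36 ± 0.22) and Lgals1, galectin-1, fell 2.66-fold (-1.41 ± 0.17). Of 13 genes for lymph node homing and egress, 6 fell and 2 rose, and 8 and 2 adjusted over the list alone (median -0.59, adjusted p = 3.54e-05, and p = 0.252 with an estimated correlation). Ccr7, the receptor that holds cells in the T zone, fell 10.7-fold (-3.41 ± 0.155), and the egress receptors S1pr1 and S1pr4 fell 3.43-fold (-1.78 ± 0.261) and 2.50-fold (-1.32 ± 0.21). Cxcr4, a receptor that positions cells in the germinal centre, rose 5.67-fold (2.50 ± 0.178). Of 18 naive and memory genes, 9 fell and 1 rose, and 11 and 3 adjusted over the list alone (median -1.40, adjusted p = 2.12e-10, and p = 0.226 with an estimated correlation). Satb1, a chromatin organiser, fell 2.92-fold from 1060.5 CPM ± 127 to 363 ± 40.9 (-1.55 ± 0.16), and Dapl1 had 1 count against 109 (ratio 86.2 in favour of non-Tfh cells, 15.2 to 3437). S1pr1 lost its call without non-Tfh T32 (adjusted p = 0.0898) or non-Tfh T53 (0.0745).

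Receptors and signalling genes moved both ways. In the IL-2 and STAT5 list 2 of 16 members rose and 6 fell, and 3 and 7 adjusted over the list alone (adjusted p = 0.0344, lower, and p = 0.552 with an estimated correlation); its mean was -0.87 but its median 0.040, and -0.16 to -0.0078 with a library left out. Socs2 fell 17.8-fold (-4.15 ± 0.533) and Socs1, both inhibitors of cytokine signalling, rose 2.69-fold (1.43 ± 0.182). Of 14 coinhibitory receptors 5 rose and 4 fell, and 7 and 7 adjusted over the list alone; the median was 0.074, the mean -0.040 and camera placed the list higher without a call (adjusted p = 0.0722). Cd160 rose 21.2-fold (4.41 ± 0.197) and Tigit rose 19.7-fold (4.30 ± 0.256). Tnfrsf14, which binds both Cd160 and Btla, rose 1.84-fold (0.88 ± 0.14), and Havcr2, TIM-3, fell 23.6-fold (-4.56 ± 0.451). The costimulation list was higher, with 5 of 19 members up and 2 down, and 6 and 2 adjusted over the list alone (median 0.14, adjusted p = 0.0147, and p = 0.552 with an estimated correlation). Tnfsf14, LIGHT, rose 3.06-fold (1.61 ± 0.151), Sh2d1a, the adaptor SAP that Tfh cells need to bind B cells, rose 2.29-fold, and Cd226, which competes with Tigit for ligands, fell 4.03-fold (-2.01 ± 0.177). The IL-2 and STAT5 call was lost without Tfh T32 (adjusted p = 0.0522), without Tfh T53 (0.106) and under a stricter filter (0.0976). The costimulation call was lost without non-Tfh T32 (0.0648) and that of Tnfrsf14 without Tfh T53 (0.0572). Without Tfh T32 the log2 fold change of Havcr2 was -3.80. The coinhibitory list passed without Tfh T32 (0.0267), without non-Tfh T53 (0.0133), under a stricter filter (0.00257) and without a filter (0.0319, with a median of -0.37).

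Of 24 T cell receptor response genes 4 rose and 1 fell, and 5 and 4 adjusted over the list alone (median -0.063, mean 0.061, camera higher, adjusted p = 0.526). Without non-Tfh T32 camera placed the list lower (median -0.37, adjusted p = 0.285), and without non-Tfh T53 the median was 0.24 (0.0505). Irf8 rose 2.74-fold (1.45 ± 0.2), Nfatc1 rose 2.18-fold (1.13 ± 0.181) and Dusp5, a phosphatase of ERK, fell 2.51-fold (-1.33 ± 0.171). Of 18 immediate early and stress genes 1 rose and 2 fell, and 1 and 3 adjusted over the list alone (median -0.28, adjusted p = 0.163, but 0.00738 without non-Tfh T32). Klf6 fell 2.61-fold, Ier2 fell 1.73-fold and Gadd45b rose 2.33-fold; Ier2 lost its call without Tfh T32 (adjusted p = 0.0819) or Tfh T53 (0.0553). Of 20 apoptosis regulators 3 rose and none fell, and 4 and 4 adjusted over the list alone (median 0.099, mean -0.021, camera higher, adjusted p = 0.677, but lower without Tfh T53, 0.997). They included Bcl2a1b, a survival gene with near-identical copies, 2.24-fold, and the death receptor Fas, 1.89-fold. Fas lost its call without Tfh T32 (adjusted p = 0.0936) or Tfh T53 (0.099).

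Of 14 TGF-beta and SMAD genes 2 fell, Smad7 and Itgae, and none rose, and adjusted over the list alone 3 fell and 1 rose (median -0.076, adjusted p = 0.0792; without Tfh T53 5.02e-04, without non-Tfh T32 0.00846, with a replicate block 0.0149). Of 14 Notch and Wnt genes 1 rose and 1 fell, and 2 and 4 adjusted over the list alone (median -0.28, mean 0.16, adjusted p = 0.5). Hes1, a Notch target, rose 15.5-fold from 0.317 CPM ± 0.290 to 5.61 ± 0.225, and Rbpj, the factor through which Notch acts, fell 1.78-fold (-0.83 ± 0.122), a call lost without Tfh T53 (adjusted p = 0.0711). Of 10 adenosine and purine receptor genes 1 rose and 2 fell, and 3 and 3 adjusted over the list alone (median -0.0057, or -0.36 to 0.12 under the alternatives, mean -0.063, camera higher, adjusted p = 0.382). Besides P2rx7, which rose, the phosphodiesterase Pde4b fell 1.64-fold (-0.71 ± 0.109) and Entpd1, the ectoenzyme CD39, fell 18.0-fold (-4.17 ± 0.895). Pde4b lost its call without Tfh T32 (adjusted p = 0.0773) or Tfh T53 (0.0708), and Entpd1 without Tfh T32 (0.0605), Tfh T53 (0.0942) or non-Tfh T53 (0.0669) and with limma-voom (0.0658); the log2 fold change of Entpd1 was -3.58 without Tfh T53 and -3.33 without non-Tfh T53.

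In the glycolysis list, which was higher, 3 of 20 members rose and 2 fell, and 9 and 3 adjusted over the list alone (median 0.49, adjusted p = 0.00999, and p = 0.742 with an estimated correlation). Hif1a, the hypoxia-inducible factor, rose 3.53-fold from 306 CPM ± 20.8 to 1079.6 ± 195, and Pfkp, a phosphofructokinase, rose 1.91-fold (0.94 ± 0.128). Aldoc, an aldolase, rose 4.64-fold (2.22 ± 0.393), and the glucose transporter gene Slc2a3 fell 1.66-fold (-0.73 ± 0.152). The list lost its call without Tfh T32 (adjusted p = 0.0522) or non-Tfh T53 (0.131). Aldoc lost its call without Tfh T53 (0.0535), and Slc2a3 without Tfh T32 (0.17), Tfh T53 (0.146) or non-Tfh T53 (0.0894); without non-Tfh T32 the log2 fold change of Aldoc was 2.96. No member passed in the lists of mitochondrial respiration (27 tested, median 0.11, adjusted p = 0.371, but 0.0115 without non-Tfh T32) and cholesterol synthesis (21 tested, median 0.053, mean -0.064, camera lower, adjusted p = 0.811), and none did adjusted over the list alone. The respiration list was placed lower without non-Tfh T53 (median -0.037, adjusted p = 0.766), and the cholesterol list higher without Tfh T53 (0.997) and without non-Tfh T32 (0.552). Atp5b measured 419 CPM ± 21.9 against 431 ± 67.6, and Srebf2, a regulator of sterol synthesis, 129.8 ± 20.3 against 117 ± 1.99.

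No member of the G2/M, G1/S and histone lists passed in either count. The 27 G2/M genes had a median of 0.35 (adjusted p = 0.0722), the 26 G1/S genes one of -0.13 (0.708) and the 14 replication-dependent histone genes, whose copies share reads, one of 0.17 (0.518). With an estimated correlation, which was 0.954, 0.870 and 0.976 in this order, the adjusted p was 0.868, 0.947 and 0.917. Mki67, a proliferation marker, measured 421 CPM ± 104 in Tfh and 329 ± 110 in non-Tfh cells (adjusted p = 0.55), Mcm6 221 ± 8.54 against 139 ± 44.8 (0.14), and Hist1h1c 272 ± 5.92 against 284 ± 69.2 (0.885). These medians rested on the non-Tfh libraries. Without non-Tfh T32 the G2/M median was 0.999, the G1/S median 0.37 and the histone median 0.82. Without non-Tfh T53 these medians were -0.040, -0.41 and -0.25. The log2 fold change of Mcm6 was 1.04 without non-Tfh T32 and 0.37 without non-Tfh T53, and that of Top2a 0.81 and -0.20. Without Tfh T32 the G2/M median was 0.55. At the preset correlation, which lies far below the estimates, the G2/M list passed camera without a count filter (adjusted p = 0.0246), and under no other setting with all 4 libraries. Without non-Tfh T32 camera placed the G2/M, G1/S and histone lists higher, and without non-Tfh T53 it placed each of them lower. Some of these fits passed the threshold, in either direction, but they hold a lone non-Tfh library.

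In 3 further lists camera called a shift though no member passed, over all genes tested or adjusted over the list alone. The estimated correlation was 0.914 in the ribosomal and 0.944 in the interferon list, far above the preset, and 0.0719 in the mitochondrially encoded list. Of the 34 cytosolic ribosomal protein genes the median was -0.33 (adjusted p = 3.79e-05, and p = 0.762 with an estimated correlation); Rpl4 measured 832 CPM ± 113 in Tfh and 1119 ± 116 in non-Tfh cells. Of the 26 interferon-stimulated genes it was -0.52 (adjusted p = 0.0107, and p = 0.785 with an estimated correlation), a call lost without Tfh T53 (0.45) or non-Tfh T32 (0.183). That median was -1.29 without Tfh T32 and -0.047 without Tfh T53; Ifi27l2a measured 317 CPM ± 224 against 333 ± 164. Of the 14 mitochondrially encoded genes it was 0.27 (adjusted p = 0.0456, and p = 0.552 with an estimated correlation), a call lost without Tfh T32 (0.0522), Tfh T53 (0.0799) or non-Tfh T53 (0.0952) and under a stricter filter (0.0579). Mitochondrial transcripts made up 22.2% and 20.4% of the counts in the Tfh libraries T32 and T53 and 19.6% and 17.2% in the non-Tfh libraries, most of them the ribosomal RNAs mt-Rnr2 and mt-Rnr1. The 10 nuclear-retained and structural RNAs had a median of -0.11 (adjusted p = 0.922), with no member past the test in either count. Camera placed this list lower, but higher with a replicate block, without Tfh T53 (median 0.31) and without non-Tfh T32 (0.20), and the median was -0.49 without Tfh T32.

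**Figure D3:**
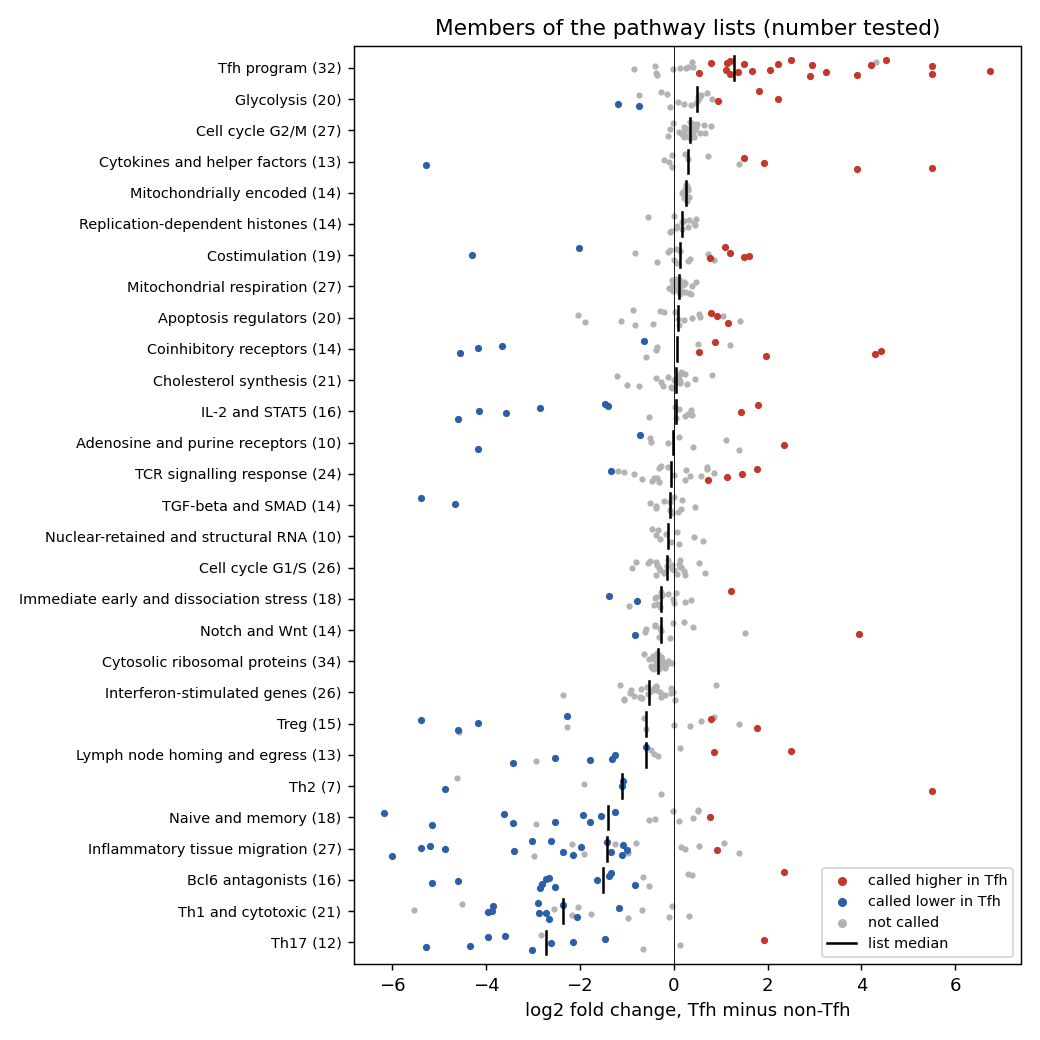
Log2 fold change (Tfh over non-Tfh) of the tested members of the 29 pathway lists, 1 point per gene, genes with no counts in a group at their bound; the black line is the median. The Tfh program had a median of 1.29, and the Th17 list one of -2.72.

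Markers of the cell types that a lymph node sort could carry over were also compared. Of 15 T cell genes 1 rose, the receptor kinase Zap70, 1.90-fold (0.93 ± 0.124), and 1 fell, Thy1, and 2 and 1 adjusted over the list alone (median 0.24, adjusted p = 0.247). Of 9 B cell genes 2 rose and 1 fell, and 3 and 4 adjusted over the list alone; the median was -1.26 and the mean -0.41, and camera placed the list higher without a call (adjusted p = 0.688). It placed the list lower, also without a call, without a count filter, with a replicate block, without Tfh T53 (median -2.06) and without non-Tfh T32, and the median was -0.42 without Tfh T32. Cd22, an inhibitory lectin of B cells, rose 11.4-fold from 12.2 CPM ± 3.70 to 137 ± 3.54 (3.51 ± 0.213, adjusted p = 0.000724). Pax5, the B cell regulator, rose 26.1-fold from 0.225 CPM ± 0.318 to 5.18 ± 0.0915, while Cd74, the invariant chain of antigen presentation, fell 4.48-fold (-2.16 ± 0.367). Ms4a1, Cd79a and Cd79b together had 2 and 4 counts in the Tfh libraries T32 and T53 and 23 and 16 in the non-Tfh libraries, so this trace of B cell RNA, 0.168 to 1.80 CPM, was higher on the non-Tfh side. The germinal centre B cell list was higher, with 2 of 5 members up and none down, and 3 and 0 adjusted over the list alone (median 0.83, adjusted p = 0.0225, and p = 0.437 with an estimated correlation). These were S1pr2, a receptor that confines cells to the follicle and is also in the Tfh program, 4.65-fold (2.22 ± 0.142), and Fas. That list lost its call without Tfh T32 (adjusted p = 0.0749), Tfh T53 (0.0632) or non-Tfh T53 (0.0525), without a low-count filter (0.0571, with a median of -0.51) and with a replicate block (0.0561). Pax5 lost its call without Tfh T32 (0.0653) or Tfh T53 (0.0561), and without non-Tfh T32 its log2 fold change was 3.48.

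Of 5 plasma cell genes 1 fell, Prdm1, which activated T cells also express, and 2 fell adjusted over the list alone (median -1.85, adjusted p = 0.0854). The list passed without Tfh T53 (0.0158, with a median of -2.83) and without non-Tfh T32 (0.0345), and without non-Tfh T53 its median was -0.18 (0.658). Of 6 macrophage and monocyte genes 1 fell in both counts, Itgam, 6.89-fold (-2.78 ± 0.605) from 2.09 CPM to 0.346 (list median -0.23, adjusted p = 0.518). That call was lost with each of the 4 libraries left out in turn (adjusted p from 0.067 to 0.261), with DESeq2 (0.126) and with limma-voom (0.0521). Of 4 CD8 T cell genes (median -2.54) Itgae and Klrc1 fell in both counts, Klrc1, an inhibitory lectin with similar neighbours, by 20.2-fold (adjusted p = 0.0146; without Tfh T32 0.109, without Tfh T53 0.071, with limma-voom 0.0661), a log2 fold change of -4.34, or -3.50 without non-Tfh T53. Of 2 NK cell genes tested Klrb1c rose in both counts, 3.12-fold (1.64 ± 0.252), while the other was lower without a call (list median -0.060). No member passed in either count among 4 dendritic cell genes, where Bst2 measured 19.9 CPM ± 11.3 against 33.1 ± 12.4, 2 endothelial genes, where Pecam1 measured 233 ± 3.99 against 220 ± 12.1, and 1 granulocyte gene, Cxcr2, with 0.766 ± 0.341 against 1.12 ± 0.0049. These lists had fewer than 5 tested members and no camera test. In the gamma delta T cell, mast cell and basophil, erythroid, lymph node stroma, and epithelial and fat tissue lists 0 members had enough counts to be tested.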

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

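The alternatives were planned, and none of the 994 calls that an alternative could test had the opposite sign under it. The counts higher and lower were 507 and 470 with RLE scaling, 525 and 468 with upper-quartile scaling, 603 and 536 with DESeq2, and 461 and 391 with limma-voom. Without a count filter they were 1006 and 980 (17991 genes tested), with a replicate block for T32 and T53 1067 and 1049, and against a minimum fold of 1.5 228 and 199, where a stricter hypothesis is tested. Leaving out 1 library gave 298 to 454 higher and 247 to 438 lower, with fewer samples in each fit, the lone sample being assumed to vary like the other group. Libraries of the same number shared some differences: deviations from the group means of libraries with the same number correlated at 0.37 across genes, which are not independent, and grouping T32 against T53 in edgeR gave 455 genes at an unadjusted p under 0.05, against 24 for the crossed grouping. Both called 0 genes, with the difference between Tfh and non-Tfh cells left in the residual, and 455 is below a 0.05 share of the 11702 genes tested. The T32 library was also the deeper one in both groups (12354113 counts against 5725358 in Tfh, 13360563 against 8636056 in non-Tfh cells). Number and depth cannot be told apart here. The shared differences favour the block, with these limits, but the labels do not say what the number marks. With an estimated correlation 0 lists were higher and 0 lower. The 10 other settings run on the lists kept 9 of the 16 list calls and lost 7 at least once. DESeq2, limma-voom, dispersions without the robust option and the minimum fold of 1.5 were not run on the lists. Of 130 named genes 106 were called, and all 106 kept their sign. The minimum fold of 1.5 was not among the settings followed for named genes. In the other settings with all 4 libraries 94 kept their call throughout, and 72 also with each library left out in turn. The 12 that lost it with all 4 libraries were Il18r1, Runx3, Ccr4, Il1rl1, Il17re, Entpd1, Klrc1, Itgam, Tbx21, Klf2, Il12rb2 and Il17ra. The fold of 21 of the 106 moved by over 1.5 times without a library, counting only fits with over 3 counts in each group. Not called and of either sign without a library were Mcm4 (-0.14 to 0.31), Atp5b (-0.19 to 0.13), Srebf2 (-0.00477 to 0.30), Ifi27l2a (-1.07 to 0.55), Hist1h1c (-0.29 to 0.21), Malat1 (-0.00564 to 0.25), Top2a (-0.20 to 0.81), Hist1h1e (-0.32 to 0.58), Atp5a1 (-0.15 to 0.22), H2-DMb2 (-0.75 to 0.24) and Vwf (-0.41 to 0.18). For other changes the cause was not tested. Depth limits genes near 1 count, worth up to 0.175 CPM.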

Other observations

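The grouping of genes by family and by chromosomal position was chosen after the called genes had been seen, as were the B cell test of Cd22 and Pax5 and the test of neighbours transcribed away from each other; the other tests below were written before their results. Gene families, taken as symbols with the same letters before the number, were unequally represented among the called genes. Of 124 families with at least 10 tested members, 6 passed Fisher's exact test after Benjamini-Hochberg adjustment, against 8.67% of genes called over all families. Interleukins and their receptors stood out, with 16 of 40 called, 3 higher and 13 lower (adjusted p = 9.38e-06), and 14 of these were already in the lists. The exact test treats genes as independent, so this p may be too small. Several of the lower genes are chromosomal neighbours that fell together: Il17a with Il17f, Il1rl1 with Il18r1 and Il18rap, and Il12rb2 with Il23r. These genes also enter the excess of neighbours given below, so both observations overlap. CD antigens followed with 15 of 55 called, 7 higher and 8 lower (adjusted p = 0.00281). Among them Cd55, which protects cells from complement, fell 14.9-fold (log2 fold change -3.90 ± 0.341, n = 2 per group, edgeR adjusted p = 0.00246; -4.61 without Tfh T32), and Cd82, a tetraspanin, rose 1.75-fold (0.81 ± 0.123), a call lost without Tfh T53 (adjusted p = 0.0553).

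Of 12 Krüppel-like factors 5 were called (adjusted p = 0.0472 by the exact test). Klf2 and Klf6 fell as given above, Klf11 fell 2.69-fold and Klf13 fell 1.64-fold, whereas Klf10, a gene induced by TGF-beta, rose 1.75-fold. Klf11 lost its call with each of the 4 libraries left out in turn (adjusted p from 0.055 to 0.159), Klf13 without Tfh T32 (0.077) or Tfh T53 (0.0947), and Klf10 without Tfh T53 (0.146) or non-Tfh T32 (0.0501). Of 15 myosin genes 6 were called, 2 higher and 4 lower (adjusted p = 0.0261). Myo1f, a class I myosin of leukocytes, fell 4.22-fold (-2.08 ± 0.199). Of 106 genes of the Fam name, which is no family by descent, 22 were called (adjusted p = 0.00366). Zinc finger genes of the Zfp name were called less often than others, 10 of 309 (3.24%, adjusted p = 0.00567).

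Cd22 and Pax5, 2 genes known from B cells, were higher in the Tfh libraries of both numbers, Cd22 at 139.7 and 134.7 CPM against 9.62 and 14.9. B cells in the Tfh sort would bring their abundant transcripts, yet Ms4a1, Cd79a and Cd79b summed to 0.316% of the Cd22 level in Tfh cells and were lower there than in non-Tfh cells, and the sort on transferred T cells would remove B cells. No counted gene overlaps Cd22, and those that overlap Pax5 reached at most 0.846% of its excess. Related genes of the Siglec and Pax families reached at most 1.14% of the excess of the gene they resemble. The counts assigned to these genes were thus too few to supply the excess. Transcription of both genes in Tfh cells may therefore be a real part of their profile, a hypothesis found and examined on the same 4 libraries. Ffar1, next to Cd22 on the same strand, had 21 counts in Tfh and 0 in non-Tfh cells, at least 8.91-fold higher, a call lost without non-Tfh T32 (adjusted p = 0.0809).

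Called genes lay next to each other on the chromosome more often than calls permuted among genes of like expression: 113 neighbouring pairs changed in the same direction, against 42.2 in the mean of the permutations (ratio 2.67, p = 0.0001, the smallest the permutations can give), and 24 in opposite directions, against 42.1. Examples were Sostdc1 with Ispd (12.8-fold higher), Jdp2 (log2 fold change 3.70 ± 0.401) with Batf (2.17-fold higher), and Il18r1 with Il18rap. The excess remained among pairs of different family names (ratio 2.49), which reads shared between genes of the same name cannot give. It also remained among pairs on opposite strands (2.37), which read-through on the same strand cannot give. Pairs transcribed away from each other without overlap had a ratio of 2.61, which reads from overlapping genes cannot give. Related genes can bear different names, however, and some of the latter pairs lie close, such as Dram1 and Gnptab 51 bp apart. Shared reads are therefore not excluded, nor are antisense reads among close pairs. Neighbours were adjacent among the tested genes, and some lay far apart. Pairs of different family names 10 to 100 kb apart had a ratio of 2.86 (39 against 13.6, permutation p = 0.0001). Those over 100 kb apart had 1.83 (18 against 9.83, permutation p = 0.01). None of these pairs overlap, which argues against antisense reads from overlap, and over 100 kb also against read-through, for these pairs only. Regulation of neighbouring genes in common may contribute, as a hypothesis from these data, and no measure of chromatin was available to test it; each technical source may still add some of the pairs.

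Changes of called genes were larger in T53 than in T32 for 61.2% of the genes higher in Tfh cells and for 64.8% of those lower. The RNA component of RNase P, Rpph1, took 0.228% and 0.286% of the counts in the T32 libraries of Tfh and non-Tfh cells and 0.0778% and 0.0683% in the T53 libraries, and Rn7sk 0.768% and 0.645% against 0.535% and 0.351%.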
